A study of Mus musculus with 18 samples.

How the data were processed

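RNA was sequenced from macrophages sorted as Tim-4low or Tim-4high from the mouse peritoneal cavity, frozen in trizol, with RNA extraction and library preparation by a service laboratory, per the labels' protocols. The labels put 18 libraries into 6 groups of 3, and every library was used. The labels call the libraries of a group triplicates, and nothing says that they came from separate animals, so p-values measure only the spread between these samples, which may be technical.

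The authors deposited estimated counts per gene and per transcript, with no normalization. The submitters' processing notes name STAR, DESeq2 and the mouse build mm10, without versions, and the quantifier's settings, the annotation release and the use of strand are not given in the sources used here. Between 62.8% and 66.8% of a library's estimated gene counts were whole to within 0.001, and the lowest row total was 10. The authors' deposited tables hold p-values and FDR values for 2 comparisons, Tim-4high over Tim-4low without a tumor and anti-Tim-4 over isotype in Tim-4high cells, and the FDR of low genes is blank. Their fold values are signed and linear, x for an increase and -x for a decrease, as deposited, and folds of the first table were turned to Tim-4low over Tim-4high. The total signal column of the authors' tables equals the sum over the 6 compared libraries of rounded counts divided by DESeq2 size factors.

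All symbols of the 23511 genes matched GENCODE M21 on mm10, 23511 with the same start and 23484 with the file's stop 1 base past the annotated end, and printed ends have that base removed. Gene identifiers came from the transcript table. Near-identical copies share reads, so counts of families such as Ear2, Chil3, Hspa1a and Hspa1b, H2-D1 and H2-K1, Cd209a and Cd209c, Ms4a4c, the Fc receptors and the Ifi genes are uncertain, as are those of overlapping or antisense genes.

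Estimated counts were rounded to whole numbers. filterByExpr kept 16609 genes and left out 6902, which held at most 0.0878% of a library's counts. edgeR 4.0.16 (R 4.3.3) fitted 1 model to all 6 groups with TMM factors and the quasi-likelihood test, with 12 residual degrees of freedom and a common dispersion of 0.0323. CPM used TMM library sizes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were Tim-4low over Tim-4high in each of 3 conditions, anti-Tim-4 over isotype and isotype tumor over no tumor in each population, and the interactions of tumor and of antibody with population.

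Camera (limma 3.58.1, preset correlation 0.01) tested 37 gene lists with at least 3 tested genes, written from general knowledge. They cover macrophage programs, metabolism and stress, markers of other cells in the cavity, and key genes of the sort and of immune checkpoints. Beside each count over all genes stands the count adjusted over the list alone.

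The naming rule took Timd4, the 8 largest changes each way among called genes with at least 10 CPM in the higher group, no overlap between groups and no predicted model or antigen receptor segment (5 each way, overlap allowed, in interactions), up to 4 members with the smallest p of each list with a call or a called member, and the key genes. It took 1155 gene results over the 9 comparisons, of which 746 were called. Not all are named, and some are not reported here. Which of the list members and key genes to name was decided after their values were seen, and each alternative's value was tabulated for 463 of the 1155. Shares of calls kept when a library was left out cover all the called genes the rule took. The groups, tests, lists, naming rule and most alternatives were set before the data were examined. Alternatives were RLE factors, no filter on low counts, robust estimation, DESeq2 1.42.0, fits of the compared groups alone, a block on library number, leaving out each library, an estimated correlation and fry. Those added later are named as such in the closing section.

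Library numbers were checked for pairing on deviations from group means. The labels number libraries within a group without saying that a number is 1 mouse. Within a condition, the Tim-4low and Tim-4high libraries of the same number correlated at 0.155 to 0.4885 in 9 pairs, each over 0.1, and those of other numbers at -0.4323 to 0.2088. All 9 correlated best with their own number, so numbers pair libraries within a condition. Across conditions the same number gave -0.2936 to 0.1237, so numbers do not pair there. Replicates differed beyond counting noise, with a chi-square per degree of freedom of 9.663 to 75.22, and none was a copy of another.

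The tests were run on simulated data with 200 changed genes per comparison. Of genes changed 2-fold, edgeR recovered 59.7%, 70.1% and 59.7% between populations without a tumor, with isotype and with anti-Tim-4, 64.2% and 61.2% for anti-Tim-4 in Tim-4high and Tim-4low cells, 53.7% and 53.7% for the tumor in the same order, and 43.3% and 40.3% for the tumor and antibody interactions. At 1.5-fold the interactions recovered 8.96% each. False calls of edgeR were 4 of 125 without a tumor, 7 of 135 and 7 of 115 for anti-Tim-4 in Tim-4high and Tim-4low cells and 6 of 83 for its interaction, and with the block 10 of 126 between the anti-Tim-4 populations, all but the first above the 0.05 aimed at. DESeq2 made 34 of 167 and 19 of 156 in the first 2. The former exceeded the limit first set, 10% of the calls plus 5, then kept for edgeR alone. Camera called a list changed 1.5-fold and 1 of 36 unchanged lists, no test of the preset correlation.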

Results

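Bulk RNA sequencing covered mouse peritoneal macrophages sorted by surface Tim-4, a phosphatidylserine receptor of tissue-resident macrophages encoded by Timd4. Tim-4low and Tim-4high macrophages came from mice without a tumor and from tumor-bearing mice given an isotype control antibody or one against Tim-4. The tumor was MC38-LG, injected into the peritoneal cavity, and MC38 is a mouse colon carcinoma line. Anti-Tim-4 was given on day 7 and cells were collected on day 10. No antibody or collection day is given for no-tumor mice, so changes with the tumor may include those of antibody or collection. Library totals lay between 24530070 and 34110392 estimated gene counts. By its title the series concerns Tim-4+ cavity macrophages and anti-tumor CD8+ T cells, and no T cell measurement was analysed here. Levels are in CPM, counts scaled to TMM library sizes, as mean ± SD of 3 libraries. Libraries are named by group and number, and a value in brackets after a gene is its log2 fold change ± standard error. Gene p-values were adjusted over 16609 genes (edgeR's quasi-likelihood test, Benjamini-Hochberg). For each gene list, the numbers of tested members that rose (up) and fell (down) stand before the adjusted p of camera.

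Timd4 (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332, mm10), the gene behind the sort, was at 108.5, 9.519 and 9.126 CPM in the no-tumor Tim-4low libraries 1 to 3. It was at 885.9, 680.3 and 622.4 CPM in Tim-4high ones. Tim-4low and Tim-4high libraries were at 14.49, 10.99 and 75.44 against 319.5, 294 and 280.4 CPM with isotype. With anti-Tim-4 they were at 28.97, 23.14 and 11.87 against 219.4, 172.8 and 168.6 CPM. Each Tim-4high library lay above every Tim-4low one, no finding between the populations since Tim-4 set the sort. Between antibodies Timd4 did not pass the test in Tim-4high (-0.67 ± 0.78, adjusted p = 0.626) or Tim-4low cells (-0.66 ± 0.80, adjusted p = 0.775). In Tim-4high cells the antibody groups did not overlap. Timd4 passed in a fit of these 6 libraries alone (-0.68, adjusted p = 0.0075), which leaves out the Tim-4low spread. DESeq2 on them gave 1.17e-08, and alternatives ran to 0.784.

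**Figure D1:**
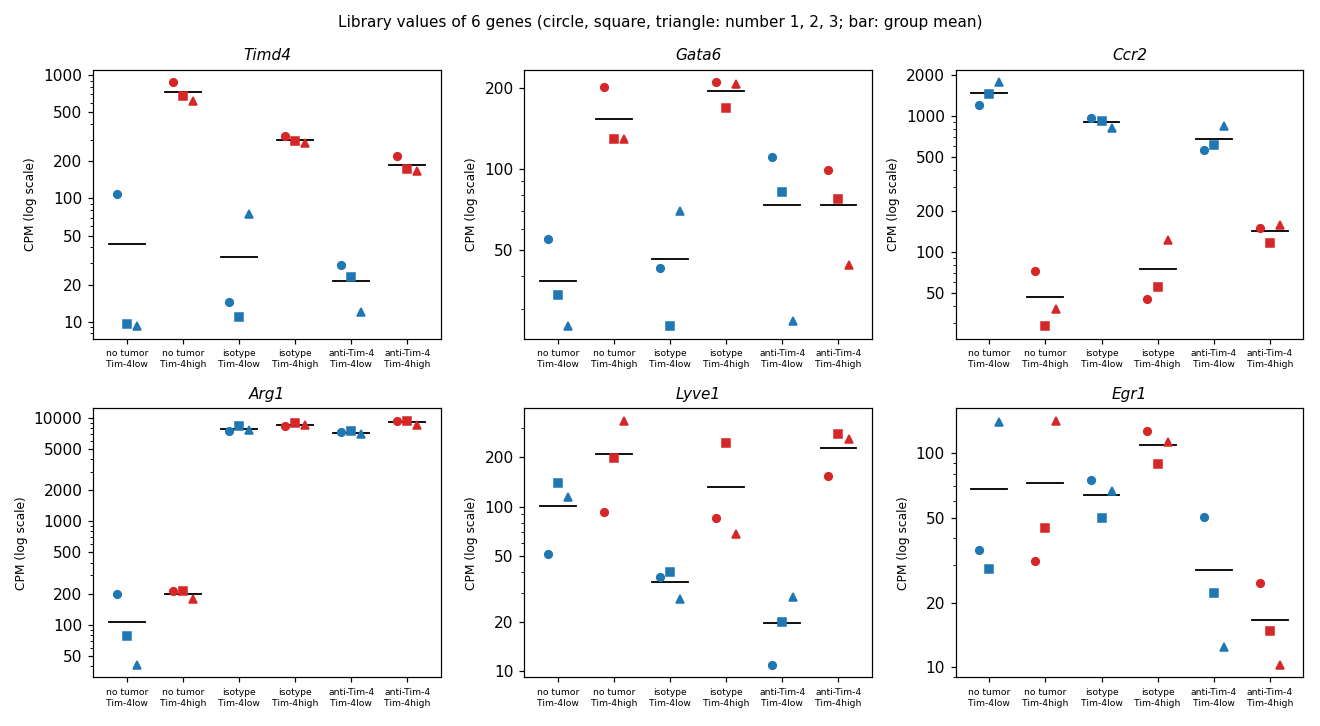
CPM on a log axis for Timd4, Gata6, Ccr2, Arg1, Lyve1 and Egr1 in the 18 libraries, with circles, squares and triangles for library numbers 1, 2 and 3, blue for Tim-4low, red for Tim-4high and a bar for the mean of 3. The mean of Gata6 was 73.5 CPM in the Tim-4low and 73.4 CPM in the Tim-4high group of anti-Tim-4 mice.

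Without a tumor, Ccr2 and H2-Eb1 were higher in Tim-4low macrophages, and Gata6 and Adgre1 higher in Tim-4high. Ccr2, the receptor for the monocyte-attracting chemokine Ccl2, was 31.5-fold higher in Tim-4low cells (1470 ± 286 CPM against 46.6 ± 23.5 CPM, log2 fold change 4.98 ± 0.41, adjusted p = 9.44e-07). The MHC class II chain gene H2-Eb1 was 9.88-fold higher (3510 ± 626 CPM against 355 ± 320 CPM, log2 fold change 3.30 ± 0.45, adjusted p = 7.25e-05). Gata6 (ENSMUSG00000005836, chromosome 18, 11052064 to 11085635), a transcription factor of large peritoneal macrophages, was lower (38.3 ± 15.1 CPM against 154 ± 41.8 CPM, log2 fold change -2.01 ± 0.46, adjusted p = 0.00478). Adgre1, which encodes F4/80, was lower too (-1.60 ± 0.33, adjusted p = 0.00226). In all, 4086 genes differed, 2118 higher and 1968 lower in Tim-4low, 655 and 703 of them by over 2-fold.

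Resident macrophage genes fell in Tim-4low cells (21 of 22 down, as many adjusted over the list alone, adjusted p = 1.16e-13, adjusted p = 0.214 with an estimated correlation). Genes of small or recruited macrophages rose (15 up and 0 down of 20, 15 and 1 adjusted over the list alone, adjusted p = 5.81e-15, adjusted p = 0.008 with an estimated correlation). Cd226 stood at 4.92 ± 0.32 (adjusted p = 2.11e-07). With a block on library number as well the list's adjusted p was 0.0768 at an estimated correlation. MHC class II presentation rose (10 up and 1 down of 14, as many adjusted over the list alone, adjusted p = 1.93e-06, adjusted p = 0.139 with an estimated correlation). So did alternative activation genes (10 up and 2 down of 20, 10 and 3 adjusted over the list alone, adjusted p = 0.00201, adjusted p = 0.139 with an estimated correlation). In that list the lectin gene Mgl2 rose (4.25 ± 0.53, adjusted p = 3.9e-05). Cholesterol synthesis genes rose (16 of 23 up, 17 adjusted over the list alone, adjusted p = 2.18e-06, adjusted p = 0.336 with an estimated correlation). Proliferation genes were higher as a list (9 of 38 up, 10 adjusted over the list alone, adjusted p = 0.000485, adjusted p = 0.853 with an estimated correlation, lost without no-tumor Tim-4high 3 at 0.0602). The list of nuclear respiratory chain genes was higher (12 of 35 up, 13 adjusted over the list alone, adjusted p = 0.00813, adjusted p = 0.853 with an estimated correlation).

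Complement genes fell in Tim-4low cells (14 of 19 down, 16 adjusted over the list alone, adjusted p = 9.79e-09, adjusted p = 0.0844 with an estimated correlation). Transcripts of the mitochondrial genome fell (12 of 13 down, 13 adjusted over the list alone, adjusted p = 1.93e-06, adjusted p = 0.295 with an estimated correlation). The lysosome list was lower (5 up and 17 down of 36, 5 and 18 adjusted over the list alone, adjusted p = 0.00103, adjusted p = 0.139 with an estimated correlation). The lipid efflux and storage list was lower (1 up and 5 down of 24, as many adjusted over the list alone, adjusted p = 0.00755, adjusted p = 0.214 with an estimated correlation). Genes for binding phosphatidylserine were lower as a list (5 up and 12 down of 25, as many adjusted over the list alone, adjusted p = 0.0219, adjusted p = 0.139 with an estimated correlation, lost without no-tumor Tim-4high 2 at 0.0841 and no-tumor Tim-4low 3 at 0.0582). Stab1 fell (-2.22 ± 0.38) and the receptor kinase gene Axl rose (1.84 ± 0.14; highest adjusted p 0.000541).

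Dendritic cell (5 of 15 up, as many adjusted over the list alone, adjusted p = 0.00305) and monocyte markers (7 up and 1 down of 15, as many adjusted over the list alone, adjusted p = 0.000956) were higher in Tim-4low cells. Their adjusted p was 0.643 and 0.139 with an estimated correlation. Plasma cell markers were higher (2 of 5 up, as many adjusted over the list alone, adjusted p = 0.00328, adjusted p = 0.133 with an estimated correlation). B cell (0.497), eosinophil (0.17), mast cell (0.545) and red cell and platelet markers (0.19) did not pass as lists, by the adjusted p in brackets. Monocyte sums were 2680 to 3590 CPM in Tim-4low and 709 to 1390 CPM in Tim-4high libraries. Summed B cell markers were at 2080 CPM in Tim-4low and 677 CPM in Tim-4high library 1, against 214 to 333 CPM in libraries 2 and 3. Of the 120 called genes of the naming rule, 108 passed in every omission, and Mertk (-0.49 ± 0.15, adjusted p = 0.024) was among the rest. Calls lost were 4, 7 and 5 without no-tumor Tim-4high 1, 2 and 3 (adjusted p up to 0.0824, 0.219 and 0.11) and 7, 4 and 12 without no-tumor Tim-4low 1, 2 and 3 (up to 0.174, 0.0656 and 0.186). Single omissions moved folds by over 1.5 times, to log2 values of 4.33 for H2-Eb1 and 4.88 for Mgl2 without no-tumor Tim-4high 2 and 1. The count was 2472 (1191 higher, 1281 lower) in a fit of these 6 libraries alone. With library number as a block, Arg1 passed (log2 fold change -1.22, adjusted p = 0.00396 against 0.0694), as it did without Tim-4low library 1 (adjusted p = 2.08e-05). The type I interferon list was then lower (adjusted p = 0.0315 against 0.245) and the immediate-early and heat shock list higher (adjusted p = 0.0322 against 0.295), with adjusted p of 0.574 and 0.493 when the correlation was estimated.

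In tumor-bearing isotype mice Ccr2 was higher and Gata6 lower in Tim-4low macrophages, and MHC class II genes did not pass as a list (1 up and 1 down of 14, 0 and 1 adjusted over the list alone, adjusted p = 0.76). Gata6 was lower in Tim-4low cells (46.2 ± 22 CPM against 196 ± 23.6 CPM, log2 fold change -2.08 ± 0.46, adjusted p = 0.00434). Adgre1 (-1.85 ± 0.33) and Icam2 (-1.62 ± 0.29) were lower too (highest adjusted p 0.00108). Ccr2 was 12-fold higher (896 ± 76.6 CPM against 74.7 ± 42.5 CPM, log2 fold change 3.58 ± 0.38, adjusted p = 4.59e-05). The scavenger receptor gene Cd163 was lower (21 ± 3.55 CPM against 125 ± 87.7 CPM, log2 fold change -2.58 ± 0.55, adjusted p = 0.00329). In all, 4011 genes differed, 1871 higher and 2140 lower in Tim-4low, 430 and 748 of them by over 2-fold.

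The resident list fell in Tim-4low cells of isotype mice (22 of 22 down, as many adjusted over the list alone, adjusted p = 1.94e-16, adjusted p = 0.22 with an estimated correlation). The small or recruited macrophage list was higher (7 up and 1 down of 20, as many adjusted over the list alone, adjusted p = 0.000427, adjusted p = 0.159 with an estimated correlation). Cd226 stood at 2.15 ± 0.28 (adjusted p = 0.000133). Lysosome genes fell (3 up and 19 down of 36, 3 and 20 adjusted over the list alone, adjusted p = 1.37e-07, adjusted p = 0.046 with an estimated correlation). The protease gene Ctsd stood at 5850 ± 862 CPM against 12600 ± 682 CPM (log2 fold change -1.11 ± 0.13, adjusted p = 5.99e-05). The list's adjusted p was 0.15 with the block and an estimated correlation. Complement genes fell (2 up and 12 down of 19, 2 and 13 adjusted over the list alone, adjusted p = 2.82e-05, adjusted p = 0.161 with an estimated correlation). Cholesterol synthesis genes were higher as a list (9 of 23 up, 12 adjusted over the list alone, adjusted p = 0.00759, adjusted p = 0.977 with an estimated correlation, lost without isotype Tim-4high 1 at 0.0572). Genes for binding phosphatidylserine were lower (2 up and 10 down of 25, 3 and 10 adjusted over the list alone, adjusted p = 0.0347, adjusted p = 0.161 with an estimated correlation, lost without isotype Tim-4high 2 at 0.101 and isotype Tim-4low 3 at 0.0545). The hypoxia factor gene Hif1a (0.96 ± 0.10) and the lipid receptor gene Trem2 (1.09 ± 0.23) rose, and the chemokine gene Ccl8 fell (-2.23 ± 0.42; highest adjusted p 0.00357). Arg1 (-0.13 ± 0.35, adjusted p = 0.83) and the PD-L1 gene Cd274 (-0.13 ± 0.61, adjusted p = 0.91) did not pass the test.

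Monocyte markers were higher in isotype Tim-4low cells (5 up and 0 down of 15, 5 and 1 adjusted over the list alone, adjusted p = 0.00103, adjusted p = 0.161 with an estimated correlation). Their summed CPM was lower there, at 4630 to 5940 against 8140 to 8370 CPM in Tim-4high. So were dendritic (260 to 495 against 752 to 962 CPM) and mast cell sums (27.7 to 84.7 against 131 to 161 CPM), lists that did not pass (adjusted p = 0.838 and 0.76). Summed T cell markers were at 210 CPM in Tim-4low and 192 CPM in Tim-4high isotype library 3, against 27.8 to 45.3 CPM in libraries 1 and 2. Of the 103 called genes of the naming rule, 78 passed in every omission. Calls lost were 16, 9 and 13 without isotype Tim-4high 1, 2 and 3 (adjusted p up to 0.188, 0.195 and 0.116) and 12, 19 and 7 without isotype Tim-4low 1, 2 and 3 (up to 0.124, 0.152 and 0.138). Without isotype Tim-4high 2, log2 fold changes were Ccl8 -1.58 and Cd163 -1.85. The count was 2625 without isotype Tim-4low 2. With library number as a block, glycolysis and hypoxia genes (adjusted p = 0.0404 against 0.165) and fibroblast markers (adjusted p = 0.0233 against 0.267) were higher as lists, with adjusted p of 0.76 and 0.516 when the correlation was estimated.

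The change from Tim-4high to Tim-4low was compared across conditions, in comparisons that share no libraries. Of the 4086 genes called without a tumor, 88.7% had the same sign in isotype mice. Both comparisons called 2114 genes with the same sign, where independent lists would share 492.2. In anti-Tim-4 mice the share was 75.9%, and 157 genes were called in both with the same sign, against 28.18.

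Tested as an interaction, the Tim-4low over Tim-4high ratio was higher in isotype than in no-tumor mice for 220 genes and lower for 367. Mgl2 (-4.28 ± 0.69), Axl (-1.52 ± 0.20) and H2-Eb1 (-2.72 ± 0.59) had lower ratios (highest adjusted p 0.0184). Stab1 (2.85 ± 0.52), Irf8 (1.79 ± 0.34) and Tgfbi (1.72 ± 0.28) had higher ratios (highest adjusted p 0.00791). Small or recruited macrophage genes (0 up and 9 down of 20, 1 and 11 adjusted over the list alone, adjusted p = 4.61e-10) and MHC class II genes (6 of 14 down, 8 adjusted over the list alone, adjusted p = 1.07e-08) had lower ratios as lists. With an estimated correlation the adjusted p was 0.0151 and 0.179. The small or recruited list had 0.176 with the block added. Mitochondrial transcripts had a higher ratio as a list (0 of 13 up, 6 adjusted over the list alone, adjusted p = 7.87e-07, adjusted p = 0.482 with an estimated correlation). Of the 60 called genes of the naming rule, 27 passed in every omission. Calls lost were 7, 13 and 24 without no-tumor Tim-4high 1, 2 and 3 (adjusted p up to 0.108, 0.108 and 0.128), 8, 13 and 31 without no-tumor Tim-4low 1, 2 and 3 (up to 0.0985, 0.0978 and 0.148), 21, 21 and 29 without isotype Tim-4high 1, 2 and 3 (up to 0.124, 0.0948 and 0.314) and 26, 28 and 20 without isotype Tim-4low 1, 2 and 3 (up to 0.117, 0.122 and 0.087). Single omissions moved folds by over 1.5 times, to log2 values of -3.75 for H2-Eb1 without no-tumor Tim-4high 2, -4.91 for Mgl2 without no-tumor Tim-4high 1. The count of 587 became 363 and 321 without isotype Tim-4low 1 and 2, 387 and 337 without isotype Tim-4high 1 and 3, 889 and 367 without no-tumor Tim-4high 1 and 3, 329 without no-tumor Tim-4low 3. It was 264 without both isotype libraries 3, 911 without both no-tumor libraries 1, 1040 with DESeq2 and 1858 with library number as a block. With that block, interferon-gamma genes had a higher ratio (adjusted p = 0.00865 against 0.117) and the immediate-early and heat shock list a lower one (adjusted p = 4.33e-05 against 0.117), with adjusted p of 0.696 and 0.214 when the correlation was estimated.

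In Tim-4high macrophages Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), which encodes the arginine-degrading enzyme arginase 1, was 42.9-fold higher in isotype tumor mice than without a tumor (8570 ± 304 CPM against 200 ± 19.2 CPM, log2 fold change 5.42 ± 0.42, adjusted p = 8.94e-08). Glycolysis and hypoxia genes rose (25 up and 0 down of 28, 26 and 1 adjusted over the list alone, adjusted p = 4.59e-41, adjusted p = 0.00461 with an estimated correlation), with the vessel growth factor gene Vegfa 32-fold higher (adjusted p = 8.41e-10). The apolipoprotein gene Apoe fell (1100 ± 195 CPM against 23500 ± 9460 CPM, log2 fold change -4.42 ± 0.33, adjusted p = 6.08e-08). Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095) rose (402 ± 25.1 CPM against 55.2 ± 66.8 CPM, log2 fold change 2.86 ± 0.65, adjusted p = 0.0018), with 4.59 without no-tumor Tim-4high 2. In all, 8548 genes differed, 4539 higher and 4009 lower with the tumor, 1600 and 1488 of them by over 2-fold.

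MHC class I (19 of 20 up, as many adjusted over the list alone, adjusted p = 1.07e-05) and class II genes (9 of 14 up, 10 adjusted over the list alone, adjusted p = 2.99e-06) rose in Tim-4high cells. An estimated correlation gave adjusted p of 0.508 and 0.163. Dendritic marker sums went from 97.7 to 340 to 752 to 962 CPM beside them and monocyte sums from 709 to 1390 to 8140 to 8370 CPM, lists that did not pass (adjusted p = 0.486 and 0.106). The immune suppression list rose (14 up and 2 down of 22, 16 and 2 adjusted over the list alone, adjusted p = 3.67e-05, adjusted p = 0.0117 with an estimated correlation). Inflammatory cytokines and chemokines rose (19 up and 1 down of 26, 20 and 1 adjusted over the list alone, adjusted p = 3.63e-07, adjusted p = 0.0914 with an estimated correlation). The interferon-gamma list was higher (5 of 28 up, 4 adjusted over the list alone, adjusted p = 0.0248, adjusted p = 0.787 with an estimated correlation, lost without no-tumor Tim-4high 1 and 3 at 0.101 and 0.0658). Proliferation genes rose (36 of 38 up, 37 adjusted over the list alone, adjusted p = 2.56e-11, adjusted p = 0.426 with an estimated correlation). Lysosome genes rose (27 up and 4 down of 36, 28 and 4 adjusted over the list alone, adjusted p = 3.26e-14, adjusted p = 0.00461 with an estimated correlation). Respiratory chain genes rose (33 up and 1 down of 35, 34 and 1 adjusted over the list alone, adjusted p = 3.26e-14, adjusted p = 0.163 with an estimated correlation). Antioxidant NRF2 (12 up and 1 down of 17, 13 and 1 adjusted over the list alone, adjusted p = 3.25e-05) and unfolded protein response genes (16 up and 4 down of 22, as many adjusted over the list alone, adjusted p = 0.00363) rose. These had an adjusted p of 0.0851 and 0.492 with an estimated correlation. Matrix and adhesion genes rose (14 up and 3 down of 23, as many adjusted over the list alone, adjusted p = 0.000773, adjusted p = 0.121 with an estimated correlation). The lipase gene Lpl (-3.24 ± 0.19) and Retnla (-3.57 ± 0.33) fell (highest adjusted p 5.82e-07). Gata6 did not pass (0.35 ± 0.44, adjusted p = 0.535).

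Resident macrophage (0.806), costimulation (0.436), Fc receptor (0.106), type I interferon (0.228), T cell (0.0956), NK cell (0.0871) and key genes (0.0516) did not pass as lists in Tim-4high cells, by the adjusted p in brackets. B cell markers fell (15 of 16 down, 16 adjusted over the list alone, adjusted p = 0.0016, adjusted p = 0.635 with an estimated correlation), with a sum of 677 CPM in no-tumor Tim-4high library 1. Fibroblast markers rose (9 of 11 up, as many adjusted over the list alone, adjusted p = 0.000633, adjusted p = 0.426 with an estimated correlation), and their sum in isotype Tim-4high library 3 was 89.9 CPM. Of the 155 called genes of the naming rule, 143 passed in every omission, and Adgre1 (0.94 ± 0.33, adjusted p = 0.0244) was among the rest. Calls lost were 5, 3 and 5 without no-tumor Tim-4high 1, 2 and 3 (adjusted p up to 0.275, 0.0814 and 0.102) and 4, 3 and 7 without isotype Tim-4high 1, 2 and 3 (up to 0.0903, 0.0916 and 0.241). A fit of these 6 libraries alone called 7287 (3627 higher, 3660 lower). Without TMM factors the median log2 fold change of all genes was -0.143 here, -0.139 for the tumor in Tim-4low cells, and 0.126 and 0.146 between the populations in no-tumor and isotype mice.

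**Figure D2:**
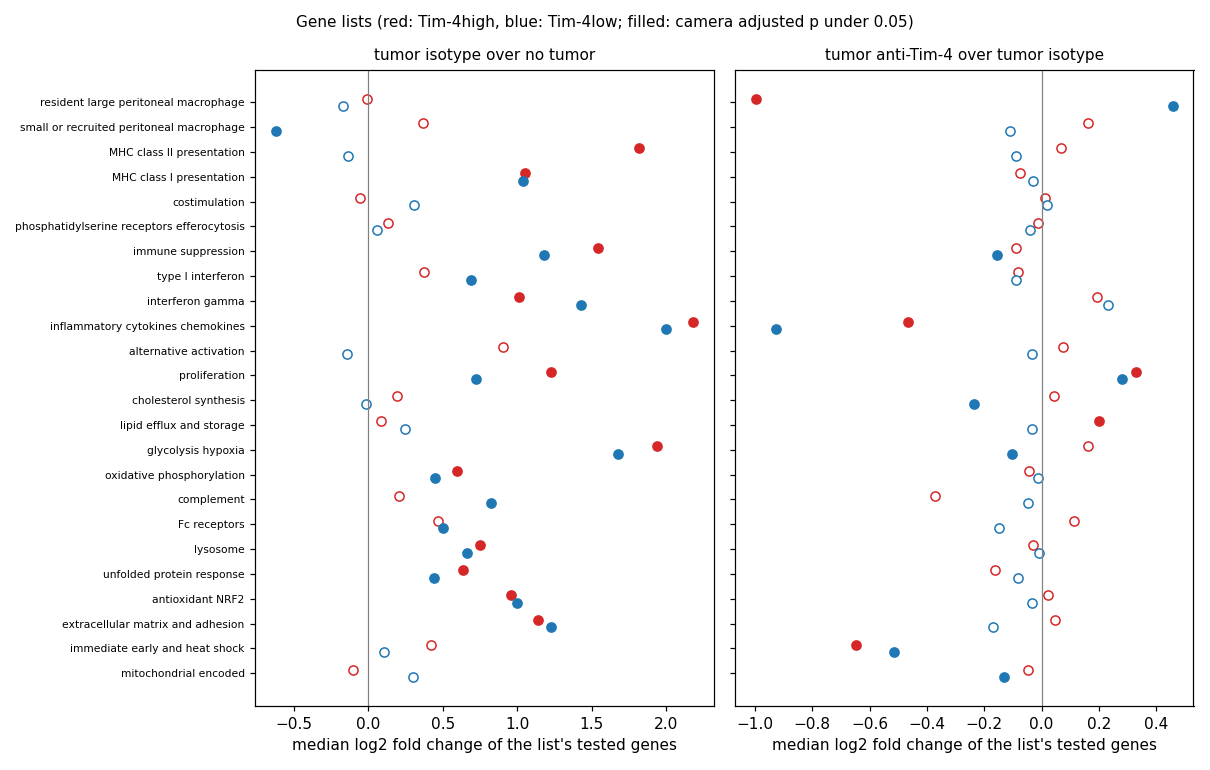
Median log2 fold change of the tested genes of 24 gene lists, for tumor isotype over no tumor on the left and tumor anti-Tim-4 over tumor isotype on the right, with red for Tim-4high and blue for Tim-4low macrophages and filled points for a camera adjusted p under 0.05. Resident macrophage genes had medians of -0.995 in Tim-4high and 0.457 in Tim-4low cells with anti-Tim-4.

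In Tim-4low macrophages of tumor mice Arg1 was 74-fold higher than without a tumor (7810 ± 543 CPM against 106 ± 82.7 CPM, log2 fold change 6.21 ± 0.43, adjusted p = 4.07e-08). Without no-tumor Tim-4low 1, at 198.7 CPM, its log2 fold change was 7.06. Glycolysis and hypoxia genes rose (26 up and 0 down of 28, 26 and 1 adjusted over the list alone, adjusted p = 8.2e-44, adjusted p = 0.00405 with an estimated correlation). The small or recruited macrophage list was lower (2 up and 9 down of 20, as many adjusted over the list alone, adjusted p = 0.00186, adjusted p = 0.139 with an estimated correlation). Cd274 rose (367 ± 20.1 CPM against 35.6 ± 25.6 CPM, log2 fold change 3.36 ± 0.67, adjusted p = 0.000654), with 4.13 without no-tumor Tim-4low 2. In all, 8273 genes differed, 4185 higher and 4088 lower with the tumor, 1385 and 1452 of them by over 2-fold.

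MHC class I genes rose in Tim-4low cells (20 of 20 up, as many adjusted over the list alone, adjusted p = 6.48e-06, adjusted p = 0.608 with an estimated correlation). Type I interferon (17 up and 2 down of 38, as many adjusted over the list alone, adjusted p = 0.00218) and interferon-gamma lists (11 of 28 up, 10 adjusted over the list alone, adjusted p = 0.000828) were higher. The adjusted p with an estimated correlation was 0.677 and 0.677. The immune suppression (14 up and 1 down of 22, as many adjusted over the list alone, adjusted p = 2.43e-06) and inflammatory lists (20 of 26 up, as many adjusted over the list alone, adjusted p = 1.28e-08) rose. Under an estimated correlation the adjusted p was 0.00405 and 0.0493. Proliferation (23 of 38 up, 24 adjusted over the list alone, adjusted p = 0.000199), lysosome (25 up and 3 down of 36, as many adjusted over the list alone, adjusted p = 1.35e-11) and respiratory chain genes (31 up and 1 down of 35, as many adjusted over the list alone, adjusted p = 1.28e-08) rose. Their adjusted p was 0.677, 0.00405 and 0.338 with an estimated correlation. Antioxidant NRF2 (12 up and 0 down of 17, 13 and 1 adjusted over the list alone, adjusted p = 3.99e-07), matrix and adhesion (16 up and 4 down of 23, as many adjusted over the list alone, adjusted p = 4.31e-05) and unfolded protein response genes (17 up and 4 down of 22, as many adjusted over the list alone, adjusted p = 0.0337) rose. With an estimated correlation the adjusted p was 0.0238, 0.0284 and 0.653. Complement (8 up and 2 down of 19, 9 and 2 adjusted over the list alone, adjusted p = 0.0204, lost without isotype Tim-4low 3 at 0.0513) and Fc receptor lists (9 up and 3 down of 13, as many adjusted over the list alone, adjusted p = 0.0184) were higher. An estimated correlation gave adjusted p of 0.531 and 0.176. Apoe (-2.87 ± 0.30) and Lpl (-2.08 ± 0.18) fell and Trem2 rose (1.86 ± 0.24; highest adjusted p 1.49e-05). Ccr2 (-0.71 ± 0.35, adjusted p = 0.0999) and Gata6 (0.27 ± 0.45, adjusted p = 0.643) did not pass the test. Ccr2 passed in a fit of these 6 libraries alone (adjusted p = 0.00773) and without both no-tumor libraries 1 (adjusted p = 0.0423).

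B cell markers fell in Tim-4low cells (16 of 16 down, as many adjusted over the list alone, adjusted p = 0.000513, adjusted p = 0.653 with an estimated correlation), with a sum of 2080 CPM in no-tumor Tim-4low library 1. Fibroblast (11 of 11 up, as many adjusted over the list alone, adjusted p = 5.6e-06) and T cell markers (13 of 20 up, as many adjusted over the list alone, adjusted p = 0.0376, lost without no-tumor Tim-4low 2 and 3 at 0.0745 and 0.103 and isotype Tim-4low 3 at 0.184) rose. These had an adjusted p of 0.311 and 0.73 with an estimated correlation. NK cell (9 of 12 up, 10 adjusted over the list alone, adjusted p = 0.0376, lost without no-tumor Tim-4low 2 and 3 at 0.0566 and 0.0635 and isotype Tim-4low 3 at 0.0834) and mesothelium and epithelium markers (7 up and 1 down of 12, 7 and 2 adjusted over the list alone, adjusted p = 0.0376, lost without no-tumor Tim-4low 2 and 3 at 0.0745 and 0.0881 and isotype Tim-4low 3 at 0.0553) rose. The adjusted p with an estimated correlation was 0.677 and 0.653. Monocyte sums went from 2680 to 3590 to 4630 to 5940 CPM, and the list did not pass (adjusted p = 0.13). In isotype Tim-4low library 3 the T cell sum was 210 CPM and the fibroblast sum 128 CPM. Without both isotype libraries 3 the T cell list did not pass (adjusted p = 0.0649). Of the 152 called genes of the naming rule, 141 passed in every omission. Calls lost were 4, 6 and 6 without no-tumor Tim-4low 1, 2 and 3 (adjusted p up to 0.483, 0.135 and 0.119) and 5, 5 and 6 without isotype Tim-4low 1, 2 and 3 (up to 0.151, 0.189 and 0.126). Of the 8548 genes called in Tim-4high cells, 94.9% had the same sign in Tim-4low cells. Both populations called 6284 genes with the same sign, where independent lists would share 2130, a value that leaves out deviations shared by paired libraries.

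**Figure D3:**
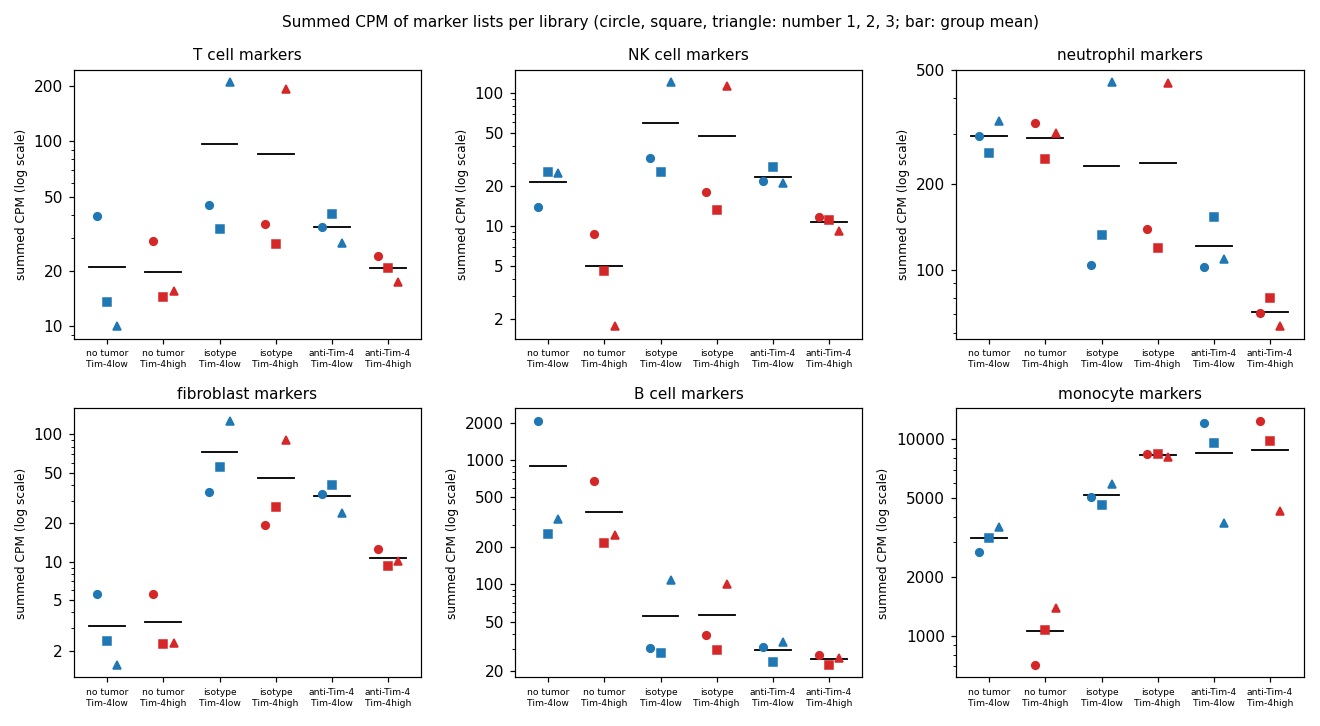
Summed CPM on a log axis of T cell, NK cell, neutrophil, fibroblast, B cell and monocyte markers in the 18 libraries, with circles, squares and triangles for library numbers 1, 2 and 3, blue for Tim-4low, red for Tim-4high and a bar for the mean of 3. T cell markers were at 210 and 192 CPM in the isotype libraries 3, and monocyte markers at 3740 and 4320 CPM in the anti-Tim-4 libraries 3.

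With anti-Tim-4, Tim-4high macrophages of tumor mice held less RNA of Thbs1 and Egr1 and more of Apoe and Mrc1. The resident list was lower (5 of 22 down, 18 adjusted over the list alone, adjusted p = 3.64e-11, adjusted p = 0.563 with an estimated correlation). The matrix glycoprotein gene Thbs1 stood at 2310 ± 567 CPM against 4880 ± 429 CPM (log2 fold change -1.08 ± 0.26, adjusted p = 0.0242). Egr1, an immediate-early transcription factor gene, was lower (16.6 ± 7.43 CPM against 109 ± 18.6 CPM, log2 fold change -2.72 ± 0.68, adjusted p = 0.0278). Apoe was 2.4-fold higher (2640 ± 339 CPM against 1100 ± 195 CPM, log2 fold change 1.26 ± 0.29, adjusted p = 0.02), and the mannose receptor gene Mrc1 3.18-fold higher (log2 fold change 1.67 ± 0.43, adjusted p = 0.0322). In all, 1324 genes differed, 715 higher and 609 lower with anti-Tim-4, 132 and 185 of them by over 2-fold. Gata6 did not pass the test (73.4 ± 27.8 CPM against 196 ± 23.6 CPM, log2 fold change -1.42 ± 0.45, adjusted p = 0.0655). The immediate-early and heat shock list was lower (1 up and 13 down of 27, 3 and 17 adjusted over the list alone, adjusted p = 6.94e-08, adjusted p = 0.563 with an estimated correlation). Fosb stood at -2.68 ± 0.49 (adjusted p = 0.00947). The list's 20 immediate-early members were all lower (median log2 fold change -0.971), and 6 of its 7 heat shock members were higher (median 0.168). The inflammatory list was lower (1 up and 8 down of 26, 2 and 10 adjusted over the list alone, adjusted p = 0.000102, adjusted p = 0.563 with an estimated correlation). The neutrophil chemokine gene Cxcl2 stood at -2.47 ± 0.46, Il1b at -2.73 ± 0.70 and the prostaglandin synthase gene Ptgs2 at -2.22 ± 0.38 (highest adjusted p 0.0302). The lipid efflux and storage list was higher (7 up and 0 down of 24, 9 and 1 adjusted over the list alone, adjusted p = 0.00241, adjusted p = 0.563 with an estimated correlation). Trem2 stood at 1.19 ± 0.23 (adjusted p = 0.0118). The proliferation list was higher (4 of 38 up, 6 adjusted over the list alone, adjusted p = 2.8e-05, adjusted p = 0.714 with an estimated correlation). Stab1 (1.48 ± 0.37) and the PD-L2 gene Pdcd1lg2 (2.11 ± 0.52) rose, and Icam2 (-1.06 ± 0.29), Ctsd (-0.58 ± 0.13) and the engulfment gene Elmo1 (-0.40 ± 0.05) fell (highest adjusted p 0.0361). Cd274 did not pass (-0.15 ± 0.61, adjusted p = 0.903). Of the 72 called genes of the naming rule, 1, Elmo1, passed in every omission. Calls lost were 18, 48 and 69 without anti-Tim-4 Tim-4high 1, 2 and 3 (adjusted p up to 0.115, 0.136 and 0.22) and 71, 9 and 56 without isotype Tim-4high 1, 2 and 3 (up to 0.174, 0.0765 and 0.296). Single omissions moved folds by over 1.5 times, to log2 values of -1.64 for Il1b without isotype Tim-4high 3, 2.27 for Mrc1 without isotype Tim-4high 2. The count became 409 and 31 without anti-Tim-4 Tim-4high 2 and 3, 10 and 203 without isotype Tim-4high 1 and 3, 210 without both isotype libraries 3 and 257 without both anti-Tim-4 libraries 3. It was 2128 (1012 higher, 1116 lower) with DESeq2, 2990 (1436 higher, 1554 lower) in a fit of these 6 libraries alone and 3194 (1525 higher, 1669 lower) with DESeq2 on them. Gata6 passed in these 3 (adjusted p = 0.0238, 0.0106 and 0.000275, over all alternatives 0.000275 to 0.261).

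Marker lists of other cells were lower in Tim-4high cells with anti-Tim-4, for T cells (0 of 20 down, as many adjusted over the list alone, adjusted p = 0.000113, lost without isotype Tim-4high 3 at 0.163) and NK cells (0 of 12 down, 9 adjusted over the list alone, adjusted p = 0.00241, lost without isotype Tim-4high 3 at 0.227). Under an estimated correlation the adjusted p was 0.714 and 0.714. Neutrophil markers were lower (4 of 13 down, 7 adjusted over the list alone, adjusted p = 0.000102, adjusted p = 0.704 with an estimated correlation). Dendritic cell (1 up and 0 down of 15, 1 and 7 adjusted over the list alone, adjusted p = 0.00241, lost without isotype Tim-4high 3 at 0.163), mesothelium and epithelium (0 up and 2 down of 12, 1 and 7 adjusted over the list alone, adjusted p = 0.00241, lost without isotype Tim-4high 3 at 0.0832) and fibroblast markers (5 of 11 down, 9 adjusted over the list alone, adjusted p = 2.8e-05) were lower too as lists, though the only dendritic member called over all genes rose. Their adjusted p was 0.714, 0.704 and 0.563 with an estimated correlation. In sums, every anti-Tim-4 Tim-4high library lay below every isotype one, at 17.3 to 23.9 against 27.8 to 192 CPM for T cells, 9.25 to 11.7 against 13.2 to 112 CPM for NK cells, 63.4 to 79.6 against 119 to 451 CPM for neutrophils, 9.31 to 12.5 against 19.6 to 89.9 CPM for fibroblasts and 259 to 377 against 752 to 962 CPM for dendritic cells, each highest in isotype library 3. Mast cell sums were 34.2 to 67.2 against 131 to 161 CPM (list adjusted p = 0.0927), and monocyte sums 12400, 9730 and 4320 against 8140 to 8370 CPM (list adjusted p = 0.792). Without both isotype libraries 3, by the adjusted p in brackets, T cell (0.0675), NK cell (0.0675), dendritic cell (0.0675) and mesothelium and epithelium markers (0.0825) did not pass.

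In Tim-4low macrophages of tumor mice 54 genes differed with anti-Tim-4, 37 higher and 17 lower, and 2046 had an unadjusted p under 0.05. Setting anti-Tim-4 libraries 1 and 2 with isotype library 3 against the other libraries called 118. Ptgs2 was lower (4.64 ± 1.08 CPM against 17 ± 2.05 CPM, log2 fold change -1.87 ± 0.37, adjusted p = 0.0435), as was the inflammasome sensor gene Nlrp3 (log2 fold change -0.51 ± 0.09, adjusted p = 0.0339). The kinase gene Sgk1 fell (-0.93 ± 0.16, adjusted p = 0.0339). Kctd21 rose (0.72 ± 0.09, adjusted p = 0.0036). Gata6 was at 73.5 ± 42.6 CPM against 46.2 ± 22 CPM and did not pass (log2 fold change 0.67 ± 0.45, adjusted p = 0.56). The inflammatory list was lower (2 of 26 down, 11 adjusted over the list alone, adjusted p = 2.59e-14, adjusted p = 0.0379 with an estimated correlation). The immediate-early and heat shock list was lower (0 up and 0 down of 27, 3 and 13 adjusted over the list alone, adjusted p = 5.86e-07, adjusted p = 0.589 with an estimated correlation). Its 20 immediate-early members were all lower (median log2 fold change -0.77), and 5 of its 7 heat shock members were higher (median 0.226). The resident list was higher (0 of 22 up, as many adjusted over the list alone, adjusted p = 0.000481, adjusted p = 0.71 with an estimated correlation, lost without anti-Tim-4 Tim-4low 1 at 0.327 and isotype Tim-4low 2 at 0.245). Proliferation genes were higher as a list (0 of 38 up, as many adjusted over the list alone, adjusted p = 0.000481, adjusted p = 0.799 with an estimated correlation, lost without isotype Tim-4low 3 at 0.265). Cholesterol synthesis (0 of 23 down, as many adjusted over the list alone, adjusted p = 0.00302) and immune suppression genes (1 of 22 down, as many adjusted over the list alone, adjusted p = 0.0381, lost without anti-Tim-4 Tim-4low 1 and 3 at 0.131 and 0.107 and isotype Tim-4low 3 at 0.152) were lower as lists. With an estimated correlation the adjusted p was 0.71 and 0.374. Glycolysis and hypoxia (0 of 28 down, 2 adjusted over the list alone, adjusted p = 0.048, lost without anti-Tim-4 Tim-4low 1 and 3 at 0.635 and 0.0598 and isotype Tim-4low 2 and 3 at 0.375 and 0.104) and mitochondrial genes (0 of 13 down, 1 adjusted over the list alone, adjusted p = 0.00758, lost without anti-Tim-4 Tim-4low 2 at 0.129 and isotype Tim-4low 3 at 0.0717) were lower too. An estimated correlation gave adjusted p of 0.799 and 0.71. Of the 17 called genes of the naming rule, 1, Kctd21, passed in every omission. Calls lost were 15, 7 and 15 without anti-Tim-4 Tim-4low 1, 2 and 3 (adjusted p up to 0.187, 0.0855 and 0.108) and 16, 16 and 13 without isotype Tim-4low 1, 2 and 3 (up to 0.219, 0.203 and 0.166). The count became 4 and 25 without anti-Tim-4 Tim-4low 1 and 3, 2, 6 and 9 without isotype Tim-4low 1, 2 and 3, 5 without both isotype libraries 3 and 29 without both anti-Tim-4 libraries 3. It was 34 without a filter, 3 (0 higher, 3 lower) in a fit of these 6 libraries alone and 295 with DESeq2.

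Marker lists were lower in Tim-4low cells with anti-Tim-4 for T cells (0 of 20 down, as many adjusted over the list alone, adjusted p = 0.000328, lost without isotype Tim-4low 3 at 0.692) and NK cells (0 of 12 down, as many adjusted over the list alone, adjusted p = 0.00254, lost without isotype Tim-4low 3 at 0.575). These had an adjusted p of 0.71 and 0.71 with an estimated correlation. Neutrophil (0 of 13 down, as many adjusted over the list alone, adjusted p = 0.0278, lost without anti-Tim-4 Tim-4low 1 at 0.139 and isotype Tim-4low 3 at 0.787) and fibroblast markers (0 of 11 down, as many adjusted over the list alone, adjusted p = 0.000481, lost without isotype Tim-4low 3 at 0.135) were lower. The adjusted p with an estimated correlation was 0.799 and 0.601. Mesothelium and epithelium (0 of 12 down, as many adjusted over the list alone, adjusted p = 0.00102, lost without isotype Tim-4low 3 at 0.0717) and monocyte markers (0 of 15 down, as many adjusted over the list alone, adjusted p = 0.0322, lost without anti-Tim-4 Tim-4low 1 at 0.119 and isotype Tim-4low 3 at 0.152) were lower. Under an estimated correlation the adjusted p was 0.589 and 0.589. Plasma cell (0 of 5 down, 1 adjusted over the list alone, adjusted p = 0.00758) and red cell and platelet markers (0 of 7 down, 3 adjusted over the list alone, adjusted p = 0.00758, lost without anti-Tim-4 Tim-4low 3 at 0.072 and isotype Tim-4low 1 at 0.136) were lower. Their adjusted p was 0.374 and 0.589 with an estimated correlation. Isotype Tim-4low library 3 had sums of 210 CPM for T cells and 455 CPM for neutrophils, and anti-Tim-4 Tim-4low library 3 of 3740 CPM for monocytes. Monocyte sums were 12100 and 9520 CPM in anti-Tim-4 Tim-4low libraries 1 and 2, above the 4630 to 5940 CPM with isotype. Without both isotype libraries 3, by the adjusted p in brackets, the T cell (0.552), NK cell (0.261), neutrophil (0.83), fibroblast (0.0511) and monocyte lists (0.101) did not pass. Of the 1324 genes called in Tim-4high cells, 45% had the same sign in Tim-4low cells, and of the 54 in Tim-4low cells 81.5% in Tim-4high cells. Both called 23 genes with the same sign, where independent lists would share 2.216, which leaves out deviations shared by paired libraries.

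In anti-Tim-4 mice the populations differed in 231 genes, 90 higher and 141 lower in Tim-4low, 57 and 39 of them by over 2-fold. Gata6 was at 73.5 ± 42.6 CPM against 73.4 ± 27.8 CPM (log2 fold change 0.00 ± 0.45, adjusted p = 0.999) and did not pass, nor did Adgre1 (-0.28 ± 0.32, adjusted p = 0.77) or Icam2 (-0.09 ± 0.28, adjusted p = 0.928). Cd163 was lower in Tim-4low cells (16.1 ± 2.69 CPM against 183 ± 46.6 CPM, log2 fold change -3.51 ± 0.57, adjusted p = 0.0103). The hyaluronan receptor gene Lyve1 was lower (log2 fold change -3.54 ± 0.57, adjusted p = 0.0103), as was Ccl8 (3.76 ± 1.55 CPM against 92.6 ± 27.8 CPM, log2 fold change -4.62 ± 0.47, adjusted p = 0.000415). Ccr2 was higher (669 ± 149 CPM against 142 ± 22.2 CPM, log2 fold change 2.23 ± 0.36, adjusted p = 0.0103), as was Cd226 (2.29 ± 0.29, adjusted p = 0.00269). The lysosome list was lower (5 of 36 down, 15 adjusted over the list alone, adjusted p = 1.41e-15, adjusted p = 0.00235 with an estimated correlation). Complement (4 of 19 down, 8 adjusted over the list alone, adjusted p = 2.12e-06), phosphatidylserine-binding (0 up and 4 down of 25, 2 and 8 adjusted over the list alone, adjusted p = 0.00484) and proliferation lists (1 of 38 down, 5 adjusted over the list alone, adjusted p = 6.41e-05) were lower. With an estimated correlation the adjusted p was 0.104, 0.104 and 0.686. The resident (1 of 22 down, 3 adjusted over the list alone, adjusted p = 0.0193, lost without anti-Tim-4 Tim-4high 1 at 0.388 and anti-Tim-4 Tim-4low 3 at 0.609) and lipid lists (1 up and 0 down of 24, 1 and 2 adjusted over the list alone, adjusted p = 0.00686, lost without anti-Tim-4 Tim-4low 1 at 0.109) were lower. An estimated correlation gave adjusted p of 0.754 and 0.21. Antioxidant NRF2 (0 of 17 down, 2 adjusted over the list alone, adjusted p = 0.0111, lost without anti-Tim-4 Tim-4low 1 at 0.173) and mitochondrial lists (0 of 13 down, as many adjusted over the list alone, adjusted p = 0.00323) were lower. These had an adjusted p of 0.224 and 0.622 with an estimated correlation. Small or recruited macrophage (4 up and 1 down of 20, 7 and 2 adjusted over the list alone, adjusted p = 7.83e-05) and costimulation genes (0 of 8 up, 1 adjusted over the list alone, adjusted p = 0.0409, lost without anti-Tim-4 Tim-4high 2 and 3 at 0.0643 and 0.0562 and anti-Tim-4 Tim-4low 2 at 0.149) were higher as lists. The adjusted p with an estimated correlation was 0.096 and 0.35. Type I interferon (1 of 38 up, as many adjusted over the list alone, adjusted p = 0.043, lost without anti-Tim-4 Tim-4high 1 and 3 at 0.0572 and 0.278 and anti-Tim-4 Tim-4low 2 at 0.284) and immediate-early and heat shock genes (0 of 27 up, as many adjusted over the list alone, adjusted p = 0.0207, lost without anti-Tim-4 Tim-4high 2 at 0.116 and anti-Tim-4 Tim-4low 1 at 0.0998) were higher too. Under an estimated correlation the adjusted p was 0.809 and 0.686. Of the 34 called genes of the naming rule, 9 passed in every omission. Calls lost were 19, 24 and 11 without anti-Tim-4 Tim-4high 1, 2 and 3 (adjusted p up to 0.13, 0.17 and 0.143) and 9, 23 and 12 without anti-Tim-4 Tim-4low 1, 2 and 3 (up to 0.145, 0.158 and 0.116). The count became 139, 34 and 125 without anti-Tim-4 Tim-4low 1, 2 and 3, 44, 25 and 96 without anti-Tim-4 Tim-4high 1, 2 and 3 and 10 without both anti-Tim-4 libraries 3. It was 445 (232 higher, 213 lower) in a fit of these 6 libraries alone, 529 with DESeq2 and 1182 with library number as a block. With that block, by the adjusted p in brackets, the folate receptor gene Folr2 (0.00313 against 0.0831), Axl (0.0181 against 0.082), Timd4 (0.0117 against 0.0881), Ms4a4c (0.00128 against 0.0698), Col1a2 (0.000426 against 0.0913) and Col1a1 (0.0107 against 0.113) passed. Each also did in the fit alone and with DESeq2 (adjusted p up to 0.0348 and 0.0215). Likewise the key gene (0.000869 against 0.0673), inflammatory (0.00447 against 0.0536), cholesterol synthesis (0.0425 against 0.109), B cell (0.0425 against 0.26) and mast cell lists (0.0425 against 0.193) passed, and plasma cells did not (0.0644 against 0.0266). When the correlation was estimated, the 5 that passed had adjusted p of 0.102 to 0.625. In that test the monocyte and fibroblast lists passed (adjusted p = 0.0343 and 0.0343).

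Marker lists were higher in Tim-4low cells of anti-Tim-4 mice for monocytes (1 of 15 up, 3 adjusted over the list alone, adjusted p = 7.83e-05) and dendritic cells (1 of 15 up, as many adjusted over the list alone, adjusted p = 0.00101). Their adjusted p was 0.104 and 0.554 with an estimated correlation. Neutrophil (0 of 13 up, as many adjusted over the list alone, adjusted p = 0.00686) and T cell markers (0 of 20 up, as many adjusted over the list alone, adjusted p = 0.0117, lost without anti-Tim-4 Tim-4high 3 at 0.058) were higher. With an estimated correlation the adjusted p was 0.634 and 0.753. NK cell (0 of 12 up, as many adjusted over the list alone, adjusted p = 0.0117, lost without anti-Tim-4 Tim-4high 3 at 0.0748) and eosinophil markers (0 of 5 up, as many adjusted over the list alone, adjusted p = 0.0145, lost without anti-Tim-4 Tim-4high 3 at 0.0838) were higher. An estimated correlation gave adjusted p of 0.686 and 0.334. Plasma cell (1 of 5 up, as many adjusted over the list alone, adjusted p = 0.0266, lost without anti-Tim-4 Tim-4high 3 at 0.0989 and anti-Tim-4 Tim-4low 1 and 3 at 0.0608 and 0.0529), mesothelium and epithelium (1 of 12 up, 3 adjusted over the list alone, adjusted p = 2.48e-05) and fibroblast markers (0 of 11 up, 6 adjusted over the list alone, adjusted p = 5.05e-07) were higher. These had an adjusted p of 0.21, 0.21 and 0.21 with an estimated correlation. Summed CPM of the mesothelium and epithelium markers was lower there, at 15.5 to 16.6 against 18.9 to 21.2 CPM. Monocyte sums were 3740 CPM in Tim-4low and 4320 CPM in Tim-4high library 3, against 9520 to 12400 CPM in libraries 1 and 2.

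Tested as an interaction, the change with anti-Tim-4 was more positive in Tim-4low than in Tim-4high cells for 277 genes and more negative for 210. The resident list had a more positive change (3 of 22 up, 19 adjusted over the list alone, adjusted p = 2.61e-14, adjusted p = 0.897 with an estimated correlation). Ctsd (0.71 ± 0.18) also had a more positive change, and Ccl8 (-2.39 ± 0.60), Stab1 (-2.23 ± 0.52), Mmp14 (-2.13 ± 0.38), Apoe (-1.75 ± 0.40) and Trem2 (-1.58 ± 0.33) had more negative ones (highest adjusted p 0.0448). None of the 33 called genes of the naming rule passed in every omission. Calls lost were 4, 33 and 33 without anti-Tim-4 Tim-4high 1, 2 and 3 (adjusted p up to 0.081, 0.111 and 0.136), 32 and 27 without anti-Tim-4 Tim-4low 1 and 2 (up to 0.163 and 0.0907), 33, 6 and 31 without isotype Tim-4high 1, 2 and 3 (up to 0.133, 0.06 and 0.0982) and 31 and 33 without isotype Tim-4low 1 and 2 (up to 0.0991 and 0.143). Ccl8 moved to -3.02 without isotype Tim-4high 2. The count of 487 became 10, 111 and 1418 without anti-Tim-4 Tim-4low 1, 2 and 3, 3 and 1 without anti-Tim-4 Tim-4high 2 and 3, 74, 1 and 735 without isotype Tim-4low 1, 2 and 3, 1 and 39 without isotype Tim-4high 1 and 3. It was 9 without both isotype libraries 3, 976 in a fit of the 12 libraries alone, 1297 with DESeq2 and 2609 with library number as a block. With that block Gata6 (adjusted p = 0.000546 against 0.0821), Adgre1 (adjusted p = 0.000471 against 0.0723) and Icam2 (adjusted p = 0.000348 against 0.0525) passed with more positive changes, as with DESeq2 (adjusted p up to 0.0239). So, by the adjusted p in brackets with the block, did the complement (0.00116), immediate-early and heat shock (0.000105), neutrophil (6.95e-05), eosinophil (0.034), dendritic cell (0.0126) and fibroblast lists (0.0401). Small or recruited macrophage (0.0304), cholesterol (0.0401), lipid (0.0164), glycolysis (0.00601), Fc receptor (0.0114) and monocyte lists (0.0494) passed with more negative ones. When the correlation was estimated, all 12 lists had adjusted p of 0.412 to 0.804.

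In the authors' deposited table for the populations of no-tumor mice, 2972 genes had an adjusted p under 0.05, and 2838 of them were called here with the same sign. In the authors' deposited table for anti-Tim-4 in Tim-4high cells there were 3163, of which 1220 were called here with the same sign. Gata6 had a signed fold of -2.67 (adjusted p = 0.000291) and Timd4 of -1.595 (adjusted p = 1.37e-08) with anti-Tim-4 in the authors' deposited table.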

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

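The tests of the 3 patterns weighed below were chosen after the result was seen, and the splits of the libraries before. An interaction test (edgeR, or camera for lists) found the contrasts of this paragraph to differ between groups. The Tim-4low over Tim-4high ratio differed between isotype and no-tumor mice in 587 genes. By adjusted p, lists with a higher ratio were mitochondrial (7.87e-07), lipid (0.00028), type I interferon (0.00289), complement (0.0467) and red cell and platelet (0.0467). Those with a lower ratio were small or recruited macrophage (4.61e-10), MHC class II (1.07e-08), proliferation (1.07e-08), respiratory chain (0.000424), dendritic cell (0.000613), alternative activation (0.00419) and cholesterol synthesis (0.0234). With an estimated correlation the small or recruited list had an adjusted p of 0.0151 (0.176 with the block on library number added) and the others 0.179 to 0.835. Genes with a higher ratio (log2 fold change) were Hgf (3.39), Spon1 (2.87), Stab1 (2.85), Cped1 (2.23), Arhgef37 (2.11), Trem2 (1.28), Irf8 (1.79), Fcgr1 (2.10), Tgfbi (1.72) and Vcan (2.05). Those with a lower ratio were Mgl2 (-4.28), Cd209c (-4.25), Ndnf (-4.11), Synpo (-3.96), Ramp1 (-3.72), Axl (-1.52), H2-Eb1 (-2.72), Irf4 (-1.16), Cd74 (-2.44), Sdc1 (-3.08) and Cd209a (-2.96). Calls were lost in the bracketed number of 12 omissions for Arhgef37 (10), Trem2, Vcan and Cd74 (9), Cd209a (8), Cd209c (6), Irf4 (4), H2-Eb1 (3), Ramp1 (1), with adjusted p up to 0.314. Single omissions moved folds by over 1.5 times, to Cd209a -2.35, Cd209c -2.88, Ndnf -3.52, Ramp1 -2.91 and Spon1 3.71 without isotype Tim-4high 3, Cd209a -3.82 without isotype Tim-4low 3, Cd209c -3.58 without no-tumor Tim-4low 3, Cd74 -3.55 and H2-Eb1 -3.75 without no-tumor Tim-4high 2, Hgf 4.15 and Vcan 2.70 without no-tumor Tim-4low 1, Mgl2 -4.91, Ndnf -4.99, Ramp1 -4.44 and Vcan 1.45 without no-tumor Tim-4high 1. The change with anti-Tim-4 differed between populations in 487 genes. It was more positive in Tim-4low cells for the resident list (2.61e-14, 0.897 with an estimated correlation) and for Col18a1 (3.09), Hhipl1 (2.96), Unc5b (2.64), Strip2 (2.59), Gfod1 (2.44), Laptm5 (0.96), Rarb (1.37) and Ctsd (0.71). It was more negative for Ccl8 (-2.39), B3gnt7 (-2.34), Stab1 (-2.23), Mmp14 (-2.13), Ggta1 (-2.08), Trem2 (-1.58), Apoe (-1.75), Hif1a (-0.80), Tgfbi (-1.34) and S100a4 (-1.64). None of these genes held in every omission, and folds moved to Ccl8 -3.02 without isotype Tim-4high 2, Col18a1 3.73 without anti-Tim-4 Tim-4high 1, Col18a1 2.37 without anti-Tim-4 Tim-4low 1.

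The resident list's median log2 fold change between populations (Tim-4low over Tim-4high) was -1.96 in isotype and -0.102 in anti-Tim-4 mice, still lower (adjusted p = 0.0193), with medians for the antibody against isotype of -0.995 in Tim-4high and 0.457 in Tim-4low cells, the last not a call without anti-Tim-4 Tim-4low 1 (adjusted p = 0.327) or isotype Tim-4low 2 (0.245). Against Tim-4low cells in the Tim-4high gate as the whole cause, 127 genes higher in isotype Tim-4low cells gave the 3 Tim-4high libraries Tim-4low shares of 25.9, 31.3 and 46.8%, below the 56.9, 74.5 and 97.1% from 19 resident genes. Tim-4high cells in the Tim-4low gate stay open, as Timd4 gave the Tim-4low libraries Tim-4high shares of -1.77, -3.97 and -8.24%, or 5.52, 3.54 and -0.297% with isotype means without libraries 3, against 43.1, 24.2 and -11.7% and 48.7, 30.6 and -3.3% from the other resident genes. That test at first asked only for overlapping ranges, which these values meet, and the need for shares above 0, met without libraries 3 in libraries 1 and 2, was added after that result was seen. A change in resident cells with the antibody may also account for the pattern and was not tested apart.

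T and NK cell lists, with no member called over all genes, were lower with anti-Tim-4 in both populations. At an estimated correlation adjusted p was 0.714 each in Tim-4high and 0.71 each in Tim-4low. Isotype libraries 3 had T cell sums of 210 and 192, Thy1 at 31.3 and 30.6 and Gzmb at 25.5 and 30.1 CPM. In other isotype libraries Thy1 and Gzmb were at most 7.01 and 5.52 CPM. Without both libraries 3 adjusted p was 0.0675 each in Tim-4high and 0.552 (T) and 0.261 (NK) in Tim-4low cells. Other cells or their RNA in these libraries may account for both calls, although a macrophage sort should remove them. Of 20 T and 12 NK markers, 1 and 0 stand in another list, and 0 reached a mean of 10 CPM over the 16 other libraries. Fewer lymphocytes with the antibody stay open, with T cell medians of -0.646 and -0.196 without these libraries, and over 11 refits the adjusted p of the lists ran from 8.46e-10 to 0.692.

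Immediate-early and inflammatory lists were lower with anti-Tim-4 in both populations (estimated-correlation adjusted p 0.563 each in Tim-4high and 0.589 and 0.0379 in Tim-4low). Against isotype libraries 3 as the whole cause, the 4 median log2 fold changes were -0.603 to -0.446 without both. The highest adjusted p was 1.21e-05, at the preset correlation only. Yet the first list's lower calls in Tim-4high cells went from 13 to 4. In Tim-4low cells 0 were called and the inflammatory median went from -0.927 to -0.548. Over 11 refits the p ran from 4.5e-17 to 0.0014. Handling that differed between antibody groups stays open. The 7 heat shock members had medians ± SE of 0.168 ± 0.255 in Tim-4high and 0.226 ± 0.351 in Tim-4low cells. That SE over genes, not libraries, decides nothing. The 20 immediate-early ones had -0.971 and -0.77. An antibody effect may account for the pattern and cannot be told apart from such handling.

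Splits of 6 libraries into 3 and 3 (for interactions with both populations of a number kept together) number 10, too few for a share under 0.05. The real split alone, 1 of 10, called as many genes in all but 1 comparison, with highest other counts of 90 against 4086 between populations without a tumor and 0 against 4011, 231, 1324, 8548, 8273, 587 and 487 in the others by edgeR. Among the 4 splits without a tumor that part all 3 pairs the highest other was 1, and 90 among the 6 that part 1. For anti-Tim-4 in Tim-4low cells 2 of 10 splits called as many as the real 54. Anti-Tim-4 libraries 1 and 2 with isotype library 3 called 118, which points to a sample structure other than the antibody.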

How the results depend on the processing

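The omissions of both libraries of a doubted number, DESeq2 on the compared libraries alone and the block with an estimated correlation were chosen after seeing the data. Every alternative set beforehand was run. For the gene results with tabulated alternatives, 5754 of 6723 alternative values kept direction and side of the threshold, 860 lost the call, 73 gained it and 36 changed sign. RLE factors and robust estimation moved no count of genes by over 1.5 times. The cause was not tested for the changes below, except that omissions leave fewer libraries.

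Counts of genes ranged over single omissions from 25 to 139 between the populations of anti-Tim-4 mice, 10 to 1160 and 2 to 40 for anti-Tim-4 in Tim-4high and Tim-4low cells, 321 to 889 and 1 to 1418 for the tumor and antibody interactions, and 2625 to 3485 between the populations of isotype mice. Without a filter anti-Tim-4 called 34 genes in Tim-4low cells. Fits of the compared libraries alone gave 2472 genes between the populations without a tumor, 445 with anti-Tim-4, 2990 and 3 for the antibody in Tim-4high and Tim-4low cells and 976 for its interaction. DESeq2 gave 529, 2128, 295 and 1297 for the last 4 and 1040 for the tumor interaction, and 3194 on the compared Tim-4high libraries alone. Without both isotype libraries 3 the counts were 210 and 5 for the antibody, 264 and 9 for the interactions. Without both no-tumor libraries 1 the tumor interaction had 911, and without both anti-Tim-4 libraries 3 the anti-Tim-4 populations differed in 10 genes and antibody counts were 257 and 29. Genes shared with the authors' deposited table for anti-Tim-4 numbered 1900 with DESeq2 and 3155 with DESeq2 on those libraries alone. Over all tested genes, 69.1% and 61% kept the no-tumor sign in isotype and anti-Tim-4 mice.

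With library number as a replicate block, the pairing within a condition gave 1182 genes between the anti-Tim-4 populations and 1858 and 2609 for the interactions, and Gata6 turned to -0.13 in the first. Beyond these and the calls given with the comparisons, the block changed no other call of a named gene, or of a list at the preset correlation, within a condition. Between conditions libraries share only a number, and the block gave 1634, 49, 8668 and 8368 genes for the antibody and the tumor in Tim-4high and Tim-4low cells. There Timd4 turned to 0.060 with the tumor in Tim-4low cells.

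Lists called with an estimated correlation numbered 1, 1 and 1 between populations without a tumor, with isotype and with anti-Tim-4, 0 and 1 for the antibody, 3 and 6 for the tumor and 1 and 0 for the interactions. With the block as well, 3 passed between the anti-Tim-4 populations and 0 between the others and for the interactions, where 8, 4, 8 and 4 lists had an unadjusted p under 0.05 in the order above. Fry called 8 with anti-Tim-4, 0 and 1 for the antibody, 25 for the tumor in Tim-4high cells and 6 and 0 for the interactions. Where both called 0, camera with an estimated correlation had 2 and 2 lists and fry 9 and 4 at an unadjusted p under 0.05, in Tim-4high cells and the interaction. The antibody interaction had 7 lists without a filter, 13 with the block, 3 without both isotype libraries 3 and 1 to 10 over single omissions. For the antibody, 7 and 7 lists passed without both isotype libraries 3 and 6 to 18 in Tim-4low cells over single omissions. Between the populations of isotype mice it was 6 to 11 lists.

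Sign changes were in genes that had not passed. Without both isotype libraries 3, Timd4 (0.75) and Pdcd1lg2 (-0.16) turned for the antibody in Tim-4low cells, Gata6 (-0.16) for the tumor and Timd4 (-0.48) in the tumor interaction. Without both no-tumor libraries 1, Timd4 turned to 1.85 with the tumor in Tim-4low cells (adjusted p = 0.0289) and Gata6 to 0.030 in the interaction. Without both anti-Tim-4 libraries 3, Icam2 turned to 0.000729 between the populations and Pdcd1lg2 to -0.10 in Tim-4low cells. Single omissions also turned signs, with log2 fold changes from -0.42 to 0.41 for Gata6, -0.33 to 0.18 for Icam2 and -0.60 to 0.045 for Adgre1 between the anti-Tim-4 populations and -1.40 to 1.09 for Cd274 without a tumor. In Tim-4low cells Timd4 ran from -1.06 to 0.74 and Pdcd1lg2 from -0.16 to 0.21 for the antibody, and Timd4 from -1.72 to 1.86 and Gata6 from -0.15 to 0.64 for the tumor. In the interactions Gata6 ran from -0.50 to 0.29 and Timd4 from -0.44 to 3.15 for the tumor, and Timd4 from -0.40 to 1.41 for the antibody. Simulated interactions had these depths and 3 libraries a group, and neither was varied.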

Other observations

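The values of 6 genes were set side by side after they were seen, so they are no test. Means in isotype Tim-4low, isotype Tim-4high and anti-Tim-4 Tim-4high libraries were for Lyve1 35, 132 ± 96.4 and 230 ± 65.5 CPM, Cd163 21, 125 ± 87.7 and 183 ± 46.6 CPM, Folr2 80.9, 73.2 ± 37.3 and 181 ± 31.7 CPM, Ccl8 8.67, 40.8 ± 26.8 and 92.6 ± 27.8 CPM, Stab1 499, 323 ± 177 and 903 ± 209 CPM and Mrc1 438, 170 ± 101 and 541 ± 70.4 CPM. The highest isotype Tim-4high library lay above the lowest anti-Tim-4 one for Lyve1 (243 against 155 CPM), Cd163 (226 against 132 CPM) and Ccl8 (70.6 against 67.9 CPM). Mast cell marker sums were 155 and 160 CPM in no-tumor Tim-4low and Tim-4high library 1.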
